A study of Solanum tuberosum with 4 samples.

How the data were processed

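Small RNA and degradome sequencing of potato tubers stored at 20 °C or 4 °C gave 4 libraries, 1 for each assay and temperature. Per the labels' protocols, total RNA was normalized and pooled for each temperature. Small RNAs were enriched with polyethylene glycol, purified from a denaturing gel, ligated to adapters at both ends and amplified by RT-PCR. Degradome libraries were built by published methods from polyadenylated RNA, per the labels. The authors deposited, per the file headers, 1 whole-number raw read count for each distinct tag sequence, with no gene name and no position. The adapter trimmer, aligner, genome build and read filters are not given in the sources used here. Tags in all 4 files were 18 to 44 nt long.

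Groups were taken from the labels. With 1 library per group no test, p-value or standard error was computed. Shares are given with exact Clopper-Pearson intervals at 95%, and ratios of shares of all reads, 4 °C over 20 °C, with exact conditional binomial intervals. Both cover the counting error of reads only. Precision was set by depth, and 3 reads corresponded to 0.155 rpm in the 20 °C small RNA library and 0.121 rpm in the 4 °C one.

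A list of 49 miRNA sequences in 35 families, with the group of targets each family is known for, was written from general knowledge before the data were examined and was not matched to a database. A tag of 19 to 23 nt was given to a family when it aligned without gaps to a listed sequence over at least 18 nt, with its 5' end within 2 nt and at most 1 mismatch. Tags that matched 2 families equally well were left out. A family was called apart where its ratio was at least 1.5-fold, its interval excluded 1 and it had at least 100 reads over both libraries. Group medians were taken over at least 3 measured families.

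Degradome 5' ends were defined by the first 18 nt of a tag. No transcripts were used, so the planned search with a mismatch penalty was replaced by its planned fallback, an exact match to the complement of miRNA positions 1 to 10, with at least 5 reads and 20 shuffles of every listed sequence as background. As 99.2% of degradome reads at 20 °C and 99.1% at 4 °C lay on ends with at least 5 reads, intervals of site ratios were also computed with the median reads of ends with at least 5 reads taken as 1 count. This was chosen after the data were seen. The floor for a site with no reads was 3 such median ends, 342 reads at 20 °C and 51 reads at 4 °C.

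Tags far higher in 1 small RNA library were taken as those of 21 and 22 nt with at least 50 reads in a library and a ratio of at least 8, with 0.5 reads added to each count. Tags were translated in all frames of both strands and matched over 6 residues to a potato virus Y coat protein sequence written from general knowledge, with the same peptide read backwards as control. Both steps were chosen after the data were seen.

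Named items followed a rule fixed before the data were examined. It took the 5 families with the most reads in each small RNA library and up to 12 in each direction among those apart. It took the 15 sites with the most reads and the 5 largest ratios in each direction among sites with at least 20 reads, and the 5 tags of 20 to 22 nt outside the families with the most reads in each library. Other families, forms and sites named were chosen after their values were seen.

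Alternatives covered mismatches, scaling, read minimums, the fold rule, the cleavage window and depth. The degradome signal of gene lists, genome-matched length profiles, penalty settings and transcript-based scalings were not run, since they need transcripts or a genome not used here. On simulated data, 261 of 261 planted family tags were recovered with 0 random tags assigned, 33 of 35 simulated family ratios lay inside their intervals, all 35 fell on the right side of the 1.5-fold rule, and 40 of 40 planted cleavage sites were found among 52 called. Planted tags and sites followed the search rules themselves, and the simulated counts held counting error only. The simulation therefore checks the code, and does not measure accuracy on the real libraries. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9.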

Results

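Small RNA and degradome libraries were compared between potato tubers stored at 4 °C and at 20 °C. The tubers came from a diploid potato line, 10908-06, and were kept for 10 days at 20 °C to set their skin before they were divided between the storage temperatures. RNA from tubers sampled after 1, 2, 5 and 15 days of storage was pooled for each temperature, per the labels, so that each of the 4 groups held 1 library. No group had a replicate, no difference between temperatures has a replicate check, and all intervals given are 95% intervals that cover counting error only. PCR reads without molecular identifiers are not independent molecules, so intervals that count each read may be too narrow even for that error. The small RNA libraries held 19336112 reads of 3908721 distinct tags at 20 °C and 24882465 reads of 5193013 distinct tags at 4 °C. The degradome libraries, which record the 5' ends of cut or decaying polyadenylated RNA, held 12180777 reads of 170303 tags at 20 °C and 13294170 reads of 464415 tags at 4 °C.

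The first comparison asked whether the size classes of tuber small RNA differed between the storage temperatures. In both libraries the 24-nt class, the usual size of the heterochromatic small interfering RNAs of plants, held the most reads, with 26.2% at 20 °C and 27.0% at 4 °C. The 21-nt class, the usual size of plant miRNAs, held 22.5% of reads at 20 °C and 20.8% at 4 °C, and the 22-nt class held 19.3% and 17.03%. The 25-nt to 28-nt classes together held 12.02% of reads at 20 °C and 15.2% at 4 °C. Exact Clopper-Pearson intervals of these shares were at most 0.0196 percentage points wide to either side.

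The ends of the size range differed most by ratio, and the 22-nt and 21-nt classes by share. Reads of 18 nt made up 1.60% of the 20 °C library and 0.884% of the 4 °C library, a ratio of 0.551 (0.548 to 0.554). Reads of 30 nt stood at a ratio of 1.85 (1.83 to 1.87) and reads of 29 nt at 1.61 (1.60 to 1.62). Reads of 34 nt were few, with 300 at 20 °C and 157 at 4 °C, and went the other way, at 0.407 (0.333 to 0.495). A 5' uridine headed 46.8% of the 21-nt reads at 20 °C and 48.4% at 4 °C, and a 5' adenosine headed 38.6% and 38.8% of the 24-nt reads. Counted by distinct tags, the 24-nt class held 47.4% of tags at 20 °C and 48.2% at 4 °C, while the differences at 18, 21 and 22 nt were smaller than by reads.

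**Figure D1:**
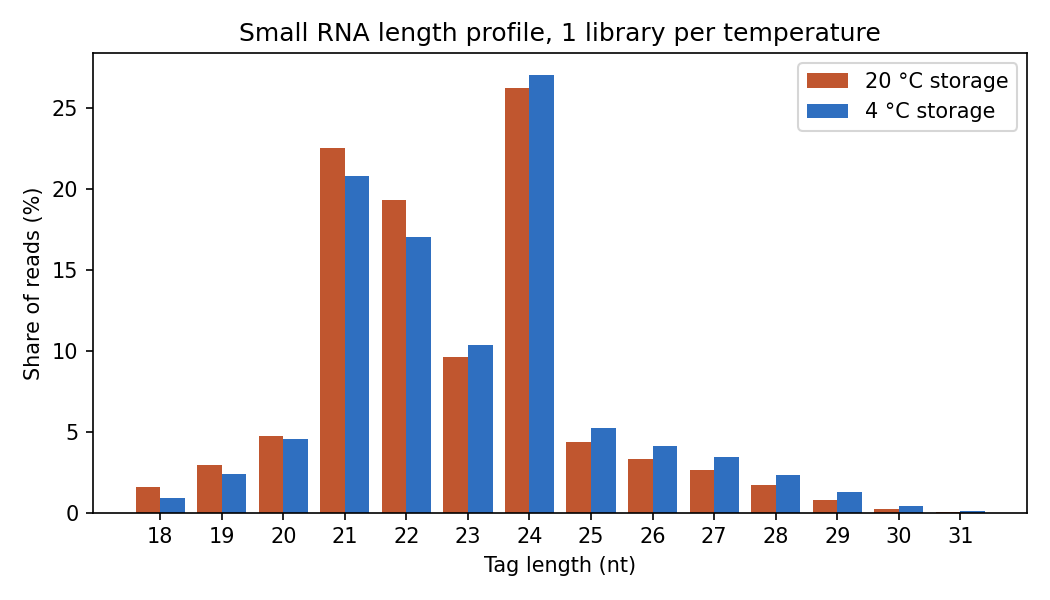
Share of reads (%) at each tag length (nt) in the 20 °C and 4 °C small RNA libraries, 1 bar per library. The 24-nt bars reach 26.2% and 27.0%, and the 18-nt bars 1.60% and 0.884%.

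The next comparison asked which known miRNA families differed in abundance. The 35 listed families took up 4.88% of reads at 20 °C (4.87% to 4.89%) and 5.04% at 4 °C (5.03% to 5.05%), a ratio of 1.03 (1.03 to 1.04). miR166, a family known to target HD-ZIP III transcription factors, was the most abundant and held 56.0% of the family reads at 20 °C and 55.6% at 4 °C. Its commonest form, TCTCGGACCAGGCTTCATTCC, began 2 nt before the listed 5' end and had 490586 reads at 20 °C and 646683 at 4 °C. Such forms made up 97.9% of miR166 reads at 20 °C and 97.0% at 4 °C.

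Of 19 families with at least 100 reads over both libraries, 4 stood at least 1.5-fold apart with an interval that excluded 1. miR394, known to target an F-box gene of leaf development, had 304 reads at 20 °C and 13 at 4 °C, 30.1-fold lower at 4 °C (17.3 to 57.2). miR159, known to target GAMYB transcription factors, had 1316 and 892 reads and was 1.90-fold lower (1.74 to 2.07). miR396, known to target growth-regulating factors, had 501 and 1218 reads and was 1.89-fold higher at 4 °C (1.70 to 2.10). miR6024, a solanaceous family directed at NBS-LRR resistance genes, had 59 and 204 reads and was 2.69-fold higher (2.00 to 3.65). Under a 2-fold rule miR394 and miR6024 remained, and miR6024 had 0 reads identical to its listed sequence in either library, so that its ratio rests almost wholly on tags 1 mismatch away, mainly TTTTAGCAAGAGTTGTTTTCCC. For scale, single 21-nt tags with at least 50 reads in either library ran from -3.28 to 6.91 in log2 ratio between the 5th and 95th percentiles. miR159 at -0.92 and miR396 at 0.92 lay inside this range. miR394 at -4.91 lay below the 5th percentile of 20-nt tags, -2.82. miR6024 at 1.43 lay above the 95th percentile of 22-nt tags, 1.09. Families pool tags, so this comparison is rough.

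The other 15 measured families lay within 1.5-fold. The most abundant were miR166 at a ratio of 1.03 (1.02 to 1.03) and miR156, known to target SPL transcription factors, at 0.984 (0.977 to 0.991), and both of these small differences changed direction under another scaling. miR168, which targets AGO1, stood at 1.17 (1.16 to 1.18), miR172, which targets AP2-like factors, at 1.36 (1.34 to 1.38), and miR6027 at 0.746 (0.737 to 0.755). Among families under 100 reads, 4 had an interval below 1 (miR319, tasiARF, miR408 and miR160) and 1 had an interval above 1 (miR399). miR319 had 46 reads at 20 °C and 16 at 4 °C, and miR399 had 11 and 35.

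**Figure D2:**
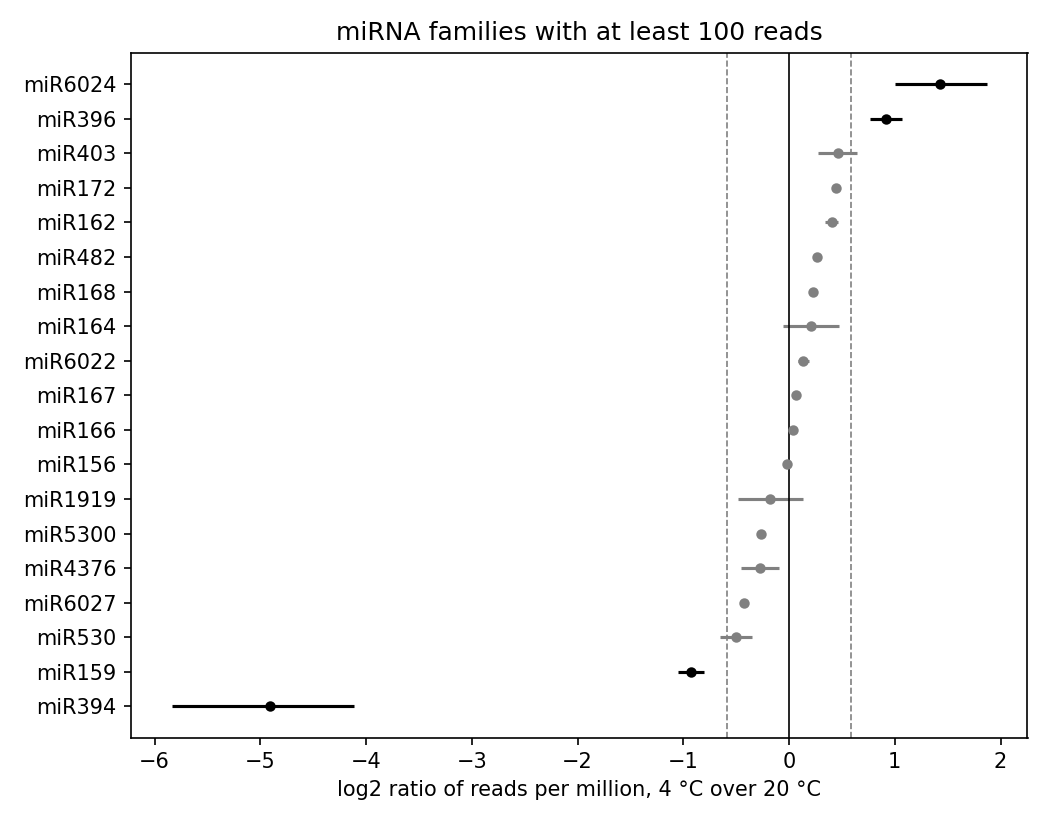
Log2 ratio of the share of all reads at 4 °C over 20 °C for the 19 miRNA families with at least 100 reads, with 95% counting intervals; black points stand at least 1.5-fold apart and dashed lines mark that limit. miR394 lies at -4.91 and miR6024 at 1.43.

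Families were then grouped by the kind of target they are known for. Those that target parts of the small RNA machinery stood higher at 4 °C in 3 of 3 cases. These were miR168, miR162 at 1.32 (1.27 to 1.38) and miR403 at 1.37 (1.21 to 1.56), with a median log2 ratio of 0.40. None of the 3 reached 1.5-fold, and 10 of all 19 measured families had an interval above 1. miR403 too was counted only through tags 1 mismatch from its listed sequence. Of 5 measured families directed at NBS-LRR or receptor genes, 3 had intervals above 1 and 2 below, with a median of 0.13. Within this group miR482 stood at 1.20 (1.17 to 1.23), and its listed forms differed, from 1.59 (1.41 to 1.79) for TCTTTCCTACTCCTCCCATACC to 1.03 (1.00 to 1.07) for TTTCCTATTCCACCCATGCCAA. Of 8 measured development and hormone families, 4 lay above 1 and 3 below, with a median of 0.05, and the sign of that median and of the NBS-LRR median each turned under 1 alternative. The 3 copper families, miR397, miR398 and miR408, had 24 reads together at 20 °C and 9 at 4 °C, and the 3 nutrient families had 17 and 44.

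Within miR156, the 20-nt form TGACAGAAGAGAGTGAGCAC stood at a ratio of 0.767 (0.752 to 0.782) and the 21-nt form TTGACAGAAGATAGAGAGCAC at 1.03 (1.02 to 1.03). Outside the listed families, the same 5 tags of 20 to 22 nt had the most reads in both libraries. GGGGATGTAGCTCAGATGGTA led with 81205 reads at 20 °C and 119728 at 4 °C, a ratio of 1.15 (1.14 to 1.16). Its forms GGGGATGTAGCTCAGATGGT and GGGGATGTAGCTCAGATGGTAG stood at 1.19 (1.18 to 1.20) and 1.33 (1.32 to 1.34). TTGGTTGAGTGAGCATCTAAG stood at 1.42 (1.40 to 1.43) and ACGTTGGGGCATGTGATTGAA at 1.01 (0.998 to 1.02). The 4 °C small RNA library also held 8440 reads that translated into segments of the potato virus Y coat protein, against 158 for the same peptide read backwards. In the 20 °C library these counts were 167 and 126. For the family ratios, an effect of a possible virus in the 4 °C tubers cannot be told apart from an effect of storage.

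The degradome libraries were compared next, as the record of which RNAs were cut. Tags of 20 and 21 nt made up 75.0% of reads at 20 °C and 65.1% at 4 °C, and tags of 18 nt made up 5.07% and 24.2%. The 20 °C library held 65824 distinct 5' ends with at least 5 reads, and the 4 °C library held 348169. The median of such ends had 114 reads at 20 °C and 17 reads at 4 °C. The libraries shared 11849 of these ends, which held 44.5% of the reads at 20 °C and 19.4% at 4 °C.

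**Figure D3:**
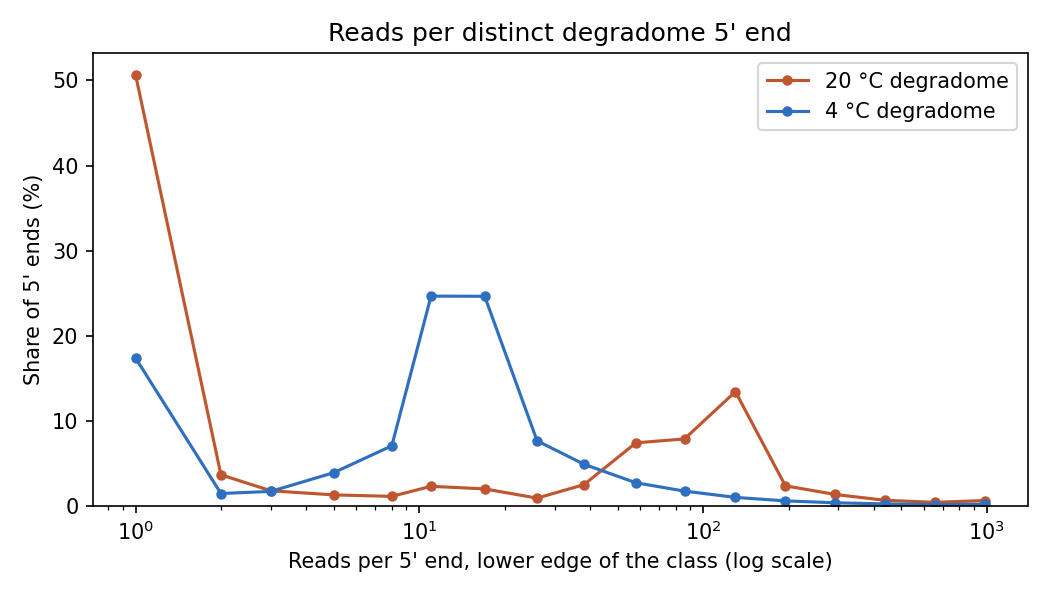
Share of distinct degradome 5' ends (%) in classes of reads per end of unequal width, on a log scale, in the 20 °C and 4 °C libraries. Apart from ends with 1 read, the fullest class began at 130 reads at 20 °C and at 11 reads at 4 °C.

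Cleavage guided by miRNAs was searched for as degradome 5' ends that begin with the exact complement of positions 1 to 10 of a listed miRNA. At 4 °C 42 such sites of 18 families had at least 5 reads, against a mean of 16.6 over 20 shuffles of the listed sequences and a highest value of 28. At 20 °C there were 12 sites of 9 families, against a shuffled mean of 3.75 and a highest value of 19, so that 1 of 20 shuffles gave as many. By reads, 1 of 20 shuffles held as many as the listed sequences in each library. The sites held 4659 reads at 4 °C and 3626 at 20 °C, against highest shuffled values of 12848 and 44994. Site counts above every shuffle were not limited to position 10. Ends that begin opposite position 8 numbered 79 at 20 °C and 372 at 4 °C, above highest shuffled values of 69 and 321. Opposite position 11 there were 14 ends at 4 °C, above a highest value of 11, and 3 at 20 °C, where 2 of 20 shuffles gave as many. Counts lay inside the shuffled range opposite position 9, with 19 ends at 20 °C and 82 at 4 °C against highest values of 41 and 93, and opposite position 12, with 1 and 2 ends against 3 and 5. Part of the sites listed here is thus matched by chance, and no single site has a check of its own. The libraries together held 48 sites of 20 families, of which 6 had reads in both.

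Sites that match miR397, a family known to target laccases, were the most read at 20 °C. The site CACTCAATGACACTCTGC had 1644 reads at 20 °C and 146 at 4 °C, 12.3-fold lower, with an interval of 4.59 to 29.8 when the median end was taken as 1 count. The site CACTCAATGACAATCTGC had 885 and 34 reads, 28.4-fold lower (5.84 to 283 on the same basis). miR397 itself had 6 reads in the 20 °C small RNA library and 4 in the 4 °C library.

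At 4 °C the most read site, GAATAGGAAAAACAAATT, matched miR482, with 1351 reads against 79 at 20 °C, a ratio of 15.7 (1.88 to 432 with the median end as 1 count). Both miR393 sites, of a family known to target auxin receptors, had reads at 4 °C alone. TCCCTTTGGATGTCTAAT had 1222 reads and stood 3.27-fold over a floor of 3 median ends at 20 °C. TCCCTTTGGATGTCTTCT had 419 reads and stood 1.12-fold over this floor, which leaves its difference near the limit of detection. Neither value includes the counting error of the 4 °C reads. miR396 matched 6 sites with 266 reads in all at 4 °C and none at 20 °C, where the floor was 342 reads, so that a difference was not detectable over this floor. The floor follows from the 114 reads of the median end at 20 °C, not from the number of reads sequenced.

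Other sites with reads in both libraries were a miR159 site, TCAATCCAAAGTTTCTGA, with 192 reads at 20 °C and 13 at 4 °C, a miR403 site, GTGAATCTAATGGGATTT, with 144 and 77, and a miR156 site, TCTTCTGTCAGCCCACTC, with 70 and 121. Intervals that took the median end as 1 count held 1 for all 3. Sites read at 20 °C alone matched miR482 (GTAGGAAAGAAAAGTGAG, 268 reads), miR164 (TGCTTCTCCAATTATGTT, 156 reads) and miR395 (AACACTTCAGAGTCTCTG, 136 reads). They stood 5.74-fold, 3.34-fold and 2.91-fold over the 4 °C floor of 3 median ends, but each had under 3 median ends of its own library. Sites read at 4 °C alone included miR156 (CTTCTGTCAACTAATTCC, 369 reads), miR398 (TGAGAACATACTTCTCAC, 126 reads), miR396 (AGCTGTGGAAGTAGATGA, 94 reads) and miR159 (TCAATCCAAATGCAACTG, 84 reads), and all 4 lay below the 20 °C floor of 3 median ends, so that a difference was not detectable over this floor. The genes cut at these sites and their positions were not analysed here, since no transcript sequence was used.

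**Figure D4:**
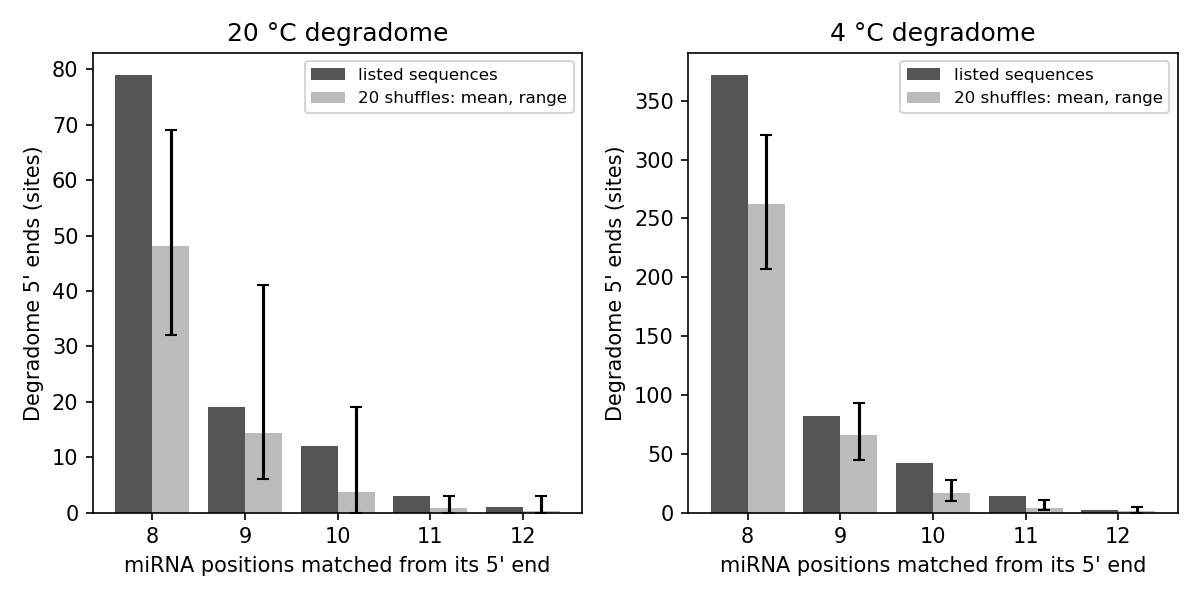
Degradome 5' ends with at least 5 reads that begin with the complement of the first 8 to 12 positions of a listed miRNA, in dark bars, and the mean of 20 shuffles with their range, in light bars, at each storage temperature. At 10 positions the counts are 12 at 20 °C and 42 at 4 °C, against highest shuffled counts of 19 and 28.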

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

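All tests weighed here were chosen after the results had been seen, and a potyvirus coat protein sequence written from general knowledge was used after the tags far higher in 1 library had been noticed.

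Patterns outside the main measurements were found in both small RNA libraries and in the 4 °C degradome library. Among tags of 21 and 22 nt with at least 50 reads, 890 stood at least 8-fold higher at 4 °C and 949 at least 8-fold higher at 20 °C. In the 4 °C small RNA library 8440 reads translated into 6-residue segments of the potato virus Y coat protein, and 2542 did so in the 4 °C degradome library. The same peptide read backwards gave 158 and 167 reads. The 4 °C degradome reads covered 41 of 262 positions. In the 20 °C degradome library 321 reads matched the peptide and 275 the backward one. In the 4 °C degradome library 10958 tags of 33 and 34 nt carried the same 11-nt segment, ACAGTAGTCCA, which no tag of these lengths carried at 20 °C. They made up 96.9% of the 11314 tags of these lengths. Whether the segment came from RNA or from library preparation was not tested. A difference in preparation between the degradome libraries therefore stays open.

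The tags at least 8-fold higher in 1 small RNA library were weighed first. The sets were unlike. The 890 tags higher at 4 °C had 126649 reads there and 563 at 20 °C. The 949 higher at 20 °C had 218977 reads there and still 21119 at 4 °C. As a check on sequencing errors, 0.337% of the 4 °C tags lay 1 substitution from a tag with at least 10 times their reads. The 8-fold rule would itself leave out error copies of tags at like levels in both libraries. This low share was thus in part fixed by the choice of tags. Forward coat protein reads outnumbered those of the same peptide read backwards 53.4-fold at 4 °C, covered 204 of 262 positions and were 94.6% of 21 and 22 nt. Small interfering RNAs of a potyvirus in the 4 °C tubers may thus account for part of the 4 °C tags. At 20 °C the same ratio was 1.33, which argues against this virus as the source of the tags of that library. Of the coat protein reads at 4 °C, 7110 were sense and 1330 antisense. Among the 4 °C tags, 9.21% overlapped the opposite strand of another tag of their set over at least 15 nt, against 4.04% of random other tags. The 20 °C values were higher, at 22.9% and 5.48%. How many of the tags are viral, what the 20 °C tags are, and whether storage or the tubers pooled made the difference were not tested.

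The second pattern is the gain of 25-nt to 30-nt reads and the loss of 18-nt reads at 4 °C. The median log2 ratio of single tags tended to rise with length from 18 to 30 nt, with a Spearman rho of 0.90 across lengths, which are not replicates. This largely restates the pattern, and a shifted gel size window and a change of small RNA size with storage cannot be told apart, since both would give such a rise and each temperature had 1 library.

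The third pattern is the small overlap of the degradome libraries. Ends with over 10 times the median reads at 20 °C were found at 4 °C in 77.5% of cases, against 11.1% of ends at or below the median, a ratio of 6.98. In the other direction 24.9% of such abundant 4 °C ends were found at 20 °C, against 1.77% of ends at or below the median. Few starting molecules amplified many times may thus account for part of the small overlap, although any cause that spares abundant ends gives a ratio in the same direction. A difference in RNA cleavage with temperature stays open and was not tested.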

How the results depend on the processing

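Allowing 1 substitution in cleavage sites and counting median ends were alternatives chosen after the data were seen. No paired analysis was possible because each group held 1 library. The same 4 families stood apart under 2 mismatches and under all 3 other scalings. Exact identity gave 3, without miR6024, which had 0 identical reads, at least 20 reads 7, at least 1000 reads 2 and the 2-fold rule 2. Counted over tags with at least 2 reads, the 4 °C minus 20 °C differences were -0.792 points at 18 nt, -1.89 at 21 nt, -2.53 at 22 nt and 0.535 at 24 nt, and over distinct tags -0.266, -0.237 and -0.332 at 18, 21 and 22 nt. The miRNA shares at 20 °C and 4 °C were 1.96% and 2.07% with exact identity, 4.94% and 5.10% with 2 mismatches and 5.93% and 6.32% of reads of 20 to 24 nt.

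Median log2 ratios under median-of-ratios scaling were 0.068 for the NBS-LRR group, -0.015 for development, -0.34 for other families and 0.34 for the machinery group, and with exact identity -0.073 for NBS-LRR and 0.12 for development, while the machinery and other groups had under 3 measured families there. miR166 stood at -0.029 under that scaling and -0.010 relative to family reads, and miR156 at 0.022 relative to reads of 20 to 24 nt. With exact identity, which kept only 5245 miR166 reads at 20 °C and 9342 at 4 °C, miR166 moved to 0.469. Cleavage sites opposite positions 9 to 12 numbered 33 at 20 °C and 136 at 4 °C, against shuffled means of 19.2 and 87.9 and highest values of 65 and 130, and with 1 substitution 137 and 701, against shuffled means of 97.3 and 512 and highest values of 143 and 673. With median ends as counts, 3 of 6 site ratios had an interval that excluded 1, against 6 by reads. Thinning the 4 °C degradome library to the 20 °C depth left 6 sites in both. This took it only from 13294170 to about 12180777 reads, so a loss of shared sites was unlikely. Thinning was not set to match distinct 5' ends, of which 348169 at 4 °C and 65824 at 20 °C had at least 5 reads. The effect of that imbalance on the sites was not tested. The cause of these shifts was not tested, apart from the scalings, which move all families together. Alternatives that need a genome or transcripts were not run. Depth limits families under 100 reads, and the reads per median end limit sites under 3 median ends.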

Other observations

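The values here were all chosen after the data were seen. The 18-nt tag GCGGGGATAGCTCAGTTG, which resembles the start of a transfer RNA but was not matched to a reference, was picked for its loss and had 35988 reads at 20 °C and 1196 at 4 °C, 38.7-fold lower (36.6 to 41.1). Its 19-nt form was 3.99-fold lower (3.85 to 4.14), while its 20-nt form stood at a ratio of 1.46 (1.34 to 1.59) and its 24-nt form at 1.18 (1.04 to 1.34). In the degradome libraries the tag CAAACGACTCTCGGCAACGG, which resembles 5.8S ribosomal RNA, had 45528 reads at 20 °C and 17 at 4 °C, while the small RNA libraries held 16107 and 24136 reads of it.

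Forms of 1 family did not always move together. The miR530 form TGCATTTGCACCTGCACCTCC had 316 reads at 20 °C and 156 at 4 °C, a ratio of 0.384 (0.315 to 0.466), and the form TGCATTTGCACCTGCACCTTT had 331 and 439, a ratio of 1.03 (0.892 to 1.19). The miR166 form TCGGACCAGGCTTCATTCCTC stood at 1.78 (1.71 to 1.85), with 3714 and 8518 reads, beside the ratio of 1.02 (1.02 to 1.03) of the commonest form. Of the 4 °C tags of 21 and 22 nt at least 8-fold higher than at 20 °C, 82.1% were 21 nt long and 737 of 890 had no read at 20 °C. Of those higher at 20 °C, 56.2% were 21 nt long and 77 of 949 had no read at 4 °C.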
